A study of Mus musculus with 12 samples.

How the data were processed

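RNA was taken from sorted prostate basal and luminal cells, frozen as pellets, with the RNeasy Mini kit, and libraries were made with the KAPA Stranded mRNA-Seq kit and sequenced on an Illumina HiSeq instrument, per the labels. Cells of 2 mice of equal age were combined for each library, and each of the 4 groups had 3 libraries. According to the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17, and aligned to mm10 and counted with Bowtie2 2.1.0 and RSEM 1.2.15. The deposited tables list 24054 genes per library with RSEM expected counts, TPM and FPKM, per the file headers. The strand setting of the counting and the gates of the sort are not given in the sources used here.

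The expected counts were rounded to whole numbers and used for all main results. TPM served 1 alternative and FPKM were not used here. Groups were assigned from the labels alone. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 14201 genes, and libraries were scaled with TMM factors. One quasi-likelihood model in edgeR 4.0.16 with a mean per group was fitted over all 12 libraries, and 5 contrasts were tested: age in basal cells, age in luminal cells, the difference of these age responses, and luminal against basal cells at 3 and at 24 months. P values were adjusted by the Benjamini-Hochberg method over all tested genes per contrast, and a gene was called at an adjusted p under 0.05. Fold changes are given as log2 values with standard errors from the fit. Means and SD are of normalized CPM over the 3 libraries of a group. The common biological coefficient of variation was 0.797.

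A group is called without a distinct fragment where the reads of each library, divided by its reads per fragment, round to 0, which leaves room for a few stray reads. For such a gene, a fold is given as a lower bound that puts 3 distinct fragments into that group, which is 2.28 CPM in young basal, 0.864 in old basal, 1.25 in young luminal and 1.58 in old luminal cells. Genes with at least 1 fragment but a lower mean under this limit get both CPM and no fold, since their fitted log2 depends on the prior count. Distinct fragments were estimated per library from the median count of genes with at least 8 reads in 1 library of a group, reads in at most 3 other libraries and a length over 500 bases.

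Gene lists of 36 cell types and processes were tested with limma's camera (version 3.58.1; inter-gene correlation preset at 0.01; log2 CPM with a prior count of 2), adjusted over the 36 lists per contrast, and again with the correlation estimated from the residuals. The fry rotation test of limma was a further alternative. The lists were basal markers, luminal markers, secretory products, progenitor and proximal luminal markers, androgen receptor targets, senescence regulators, senescence-associated secretory genes, proliferation, interferon-stimulated genes, class I and class II antigen presentation, chemokines, complement, NF-kB targets, acute-phase genes, immediate-early genes, heat shock, unfolded protein response, glutathione and oxidative defense, oxidative phosphorylation, ribosomal proteins, cholesterol, polyamines, basement membrane and matrix, Notch, Wnt, and markers of T and NK cells, B cells, macrophages, fibroblasts, smooth muscle, endothelium, erythroid cells, seminal vesicle, neuroendocrine cells and urothelium. The overlap of the age responses was tested with Fisher's exact test.

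The model, filter, threshold, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule names, per age comparison, the 10 largest rises and 10 largest falls with an adjusted p under 0.05, no overlap of the 3 old and 3 young libraries and a mean of at least 5 CPM in the higher group. It names 5 in each direction for each cell type comparison and for the difference of the age responses, 15 fixed genes, and up to 4 called members of each list by smallest p. By chance alone, 10% of genes have 3 against 3 libraries that do not overlap. Other genes named, mostly remaining called members of a list and genes called in both cell types, were chosen after their values were seen, and some genes that the rule names are not reported.

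Genes with reads at multiples of a fixed size were noticed after the data were examined, a pattern that was not itself tested. An analysis of fragment-equivalent counts was then added, with reads divided by the estimated reads per fragment and a filter of minimum count 3 and minimum total 10. It kept 11189 genes and had a common biological coefficient of variation of 0.116. The first estimator, the peak of the count distribution, was replaced after results under it had been seen, because on simulated libraries it gave 1.09 to 9.34 times the true value, against 0.98 to 1.24 times for the median of genes seen in 1 library. With less variable simulated amplification the peak gave 1.04 to 3.67 and 0.994 to 1.19 times the true value, and the median 0.983 to 1.29 and 0.973 to 1.18 times. The setting of that simulation was loosened for a time and then put back. Results under both estimators are given. Medians of lists with genes at 0 put at their bound were also added after the data were examined. The tests of thinned libraries and of converging cell types were first computed with the peak.

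The pipeline was tested on simulated reads with 200 changed genes, all drawn from tested genes with at least 20 CPM. The shares called do not cover genes below that level. Apart from the changed genes, all simulated libraries had the same mean per gene, averaged over all libraries. The shares are therefore not specific to the profile of basal or luminal cells. Of genes changed 4-fold the pipeline called 87.9% for the basal and for the luminal age contrast and 63.6% for the difference of the responses. Of genes changed 2-fold it called 26.9%, 38.8% and 17.9%, and false calls were 2 of 83, 3 of 92 and 3 of 57. When simulated fragments were amplified into reads instead, the same fit called 98.5%, 98.5% and 89.4% of 4-fold and 46.3%, 55.2% and 32.8% of 2-fold changes, with 7 of 116, 1 of 114 and 7 of 93 false calls. On fragment-equivalent counts of the same reads, 11 of 131, 7 of 139 and 11 of 104 calls were false, a higher share in each. Between cell types the main fit called, on reads that were not amplified, 87.9% and 84.8% of 4-fold changes at 3 and 24 months, with 6 of 94 and 3 of 90 false calls. The simulated cell types differed in 200 genes, against 5341 and 5028 called in the data.

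Expected counts of near-identical genes, such as Svs3a and Svs3b, Gsta1 and Gsta2, H2-Q genes, Amy1, Ren1 and Ren2, Rpl26, Gm20752, and the pseudogene Tmem181c-ps, are uncertain. Coordinates were taken from the GRCm38 annotation by symbol, which matched 13396 of 14201 tested genes. R 4.3.3, DESeq2 1.42.0 and Python 3.11.15 were also used.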

Results

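Basal and luminal epithelial cells sorted from the prostates of young (3 months) and old (24 months) C57BL/6 mice were compared by RNA sequencing, with n = 3 libraries per group and 2 mice pooled in each library. The 12 libraries held 20012691 to 27663450 counted reads and 11706 to 13744 genes above 0. Cell type was the main difference between libraries. On the 6270 genes with at least 20 CPM (read counts scaled to equal library totals), the first principal component took 80.9% of the variance and separated basal (-78.1 to -64.4) from luminal libraries (67.7 to 75.4). The second component took 4.12% and separated young from old libraries. Over all 14201 tested genes, the first component took 45.3% and the second 8.27%. There the second component set basal young replicate 1 (158.9) apart from the other libraries (-43.3 to 28.4) and did not separate the other young from old basal libraries. Within a group, libraries correlated at Pearson r = 0.844 to 0.929, against 0.689 to 0.741 between cell types. Young against old libraries of the same cell type correlated at 0.846 to 0.889, which lies within the range of replicates. Genes with at least 8 reads in a single library of a group had a median of 16.2 to 73.5 reads, depending on the library. That median was taken as the number of reads that copies of 1 fragment made by PCR would give. By that estimate, young basal libraries held 373055 to 564877 distinct fragments and old basal libraries 687032 to 1428262. Young luminal libraries held 721157 to 847773 and old luminal libraries 543420 to 728546. Reads of replicate libraries scattered 35 to 150 times more than independent counts would (chi-square per degree of freedom), which includes differences between mice. Floors given with fold changes cover counting error only, because reads without molecular identifiers include PCR copies, while the SE of fitted fold changes also carries the spread between libraries.

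**Figure D1:**
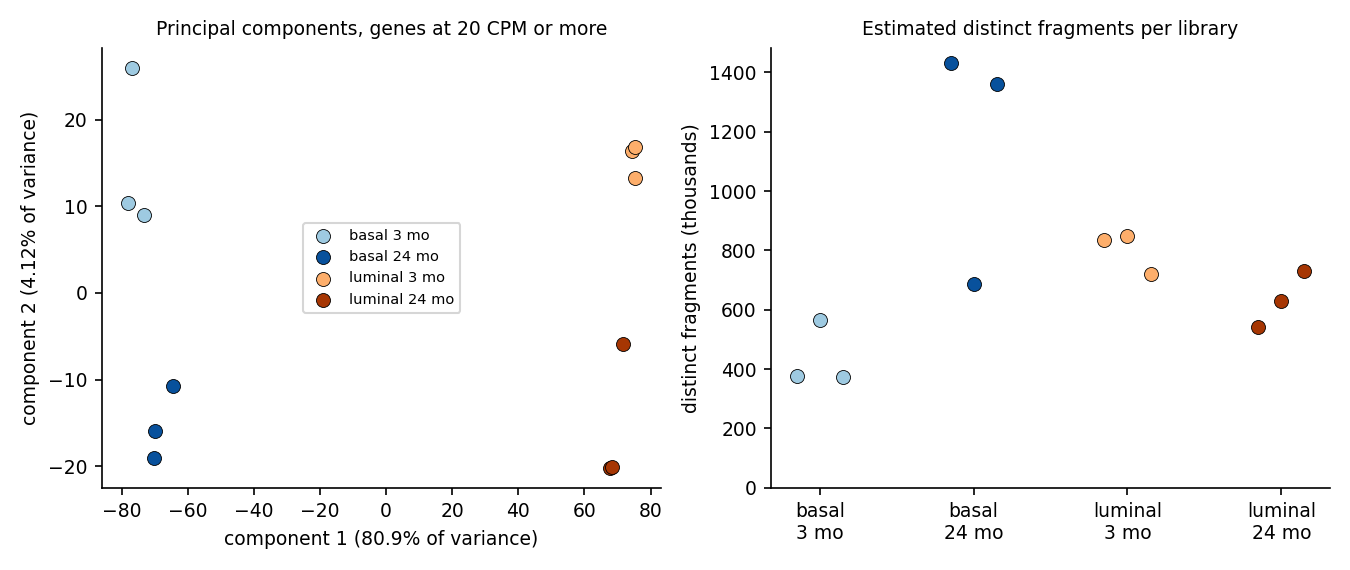
Principal components of the 12 libraries on genes with at least 20 CPM, and the estimated number of distinct fragments per library. Cell types separate on the first component and ages on the second, and old basal libraries hold more fragments than young ones.

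Keratin 5, the usual marker of prostate basal cells, was at 2410 ± 255 CPM in young basal cells and 7.79 ± 0.897 CPM in young luminal cells (mean ± SD, n = 3; log2 fold change -8.27 ± 0.21 SE, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 5.02e-12). Krt14 (log2 fold change -7.57), Col17a1 (-10.40), the hemidesmosomal linker Dst (-3.81) and the Notch ligands Jag1 (-5.03) and Jag2 (-5.82) were lower in young luminal cells, and Trp63 was at least 45.7-fold lower. Luminal cells had more Cldn3 (25.3 against 1105 CPM, log2 5.45 ± 0.26, edgeR adjusted p = 8.01e-10), Hoxb13 (2.94), the secretory genes Tgm4 (4.68), Defb50 (3.53) and Svs2 (6.71), and the endoplasmic reticulum genes Sdf2l1 (4.53) and Pdia6 (2.53). Of 14201 tested genes, 2704 were higher and 2637 lower in luminal cells at 3 months, and 2226 were higher and 2802 lower at 24 months. These totals stayed at 4588 to 5156 and 4248 to 4527 without any 1 library. At 24 months Krt5 (-7.84, edgeR adjusted p = 1.46e-11), Krt14 (-7.07), Jag1 (-5.58), Cldn3 (4.86), Tgm4 (5.21) and Svs2 (6.95) kept these differences. The 3 luminal libraries lay entirely on 1 side of the 3 basal libraries for each of these genes at the ages given, which the naming rule required of Trp63.

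Comparison of the cell types tests whether the sorted fractions carry their known markers. By fitted log2, genes from a group without a distinct fragment came first, and their folds are lower bounds that give no rank. At 3 months they were the higher luminal Ren2 (at least 20.5-fold), Gm20752 (17.1), Ms4a5 (12.6), Cyp21a1 (11.5) and Pde9a (11.4) and the lower luminal Mafa (13.4), Pecam1 (12.5), 2610018G03Rik (11.3) and Vwa7 (11.1). At 24 months they were the higher luminal Ren2 (at least 101-fold), Gabrp (25), Treh (20.6), Ctse (19.2) and F5 (19) and the lower luminal Tmem181c-ps (32.3), Dio3 (16.6), Itga9 (14.6), Nrg2 (14) and Rpl26 (13). Rpl26 is the only named gene of these comparisons whose call ended under another setting (edgeR adjusted p = 0.011 with all 12 libraries, up to 0.088). Foxa1, an androgen receptor cofactor listed here as a luminal marker, was lower in luminal cells at 3 (log2 -1.73) and 24 months (-1.35). The stromal proteoglycan Dcn was lower in luminal cells (-4.06 and -4.52).

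Among 36 gene lists, basal epithelial markers were lower in luminal cells at 3 months (22 of 24 called lower, camera adjusted p = 8.43e-18) and at 24 months (7.06e-14). Their camera adjusted p was 0.00851 and 0.0207 with an estimated correlation between genes. Luminal markers were higher at both ages (15 genes higher and 2 lower at 3 months, camera adjusted p = 4.51e-05 and 3.51e-06), with adjusted p = 0.0287 and 0.0341 with an estimated correlation. Immediate-early genes (camera adjusted p = 4.12e-07 and 3.37e-06), basement membrane and matrix genes (1.86e-08 and 9.14e-06) and Notch genes (0.000647 and 0.00046) were shifted lower in luminal cells at both ages. With an estimated correlation, camera adjusted p was 0.0287 and 0.0363 for immediate-early and for Notch genes, and 0.0235 and 0.0363 for matrix genes. Secretory genes (10 of 12 higher), unfolded protein response genes (23 of 27 higher) and seminal vesicle genes (10 of 10 higher) were higher at both ages. With an estimated correlation, their camera adjusted p was 0.0885, 0.0885 and 0.238 at 3 months and 0.0721, 0.0695 and 0.12 at 24 months. Ribosomal protein genes (54 and 63 of 70 lower), NF-kB targets, heat shock genes and endothelial genes were shifted lower at both ages. With an estimated correlation, their camera adjusted p was 0.184, 0.0701, 0.17 and 0.0527 at 3 months and 0.134, 0.238, 0.235 and 0.0753 at 24 months. At 3 and not at 24 months, oxidative phosphorylation genes (camera adjusted p = 0.0199) and neuroendocrine genes (0.0201) passed as shifted higher in luminal cells. Senescence-associated secretory genes passed as shifted lower at 3 months only (camera adjusted p = 0.00586). With an estimated correlation, camera adjusted p was 0.0583, 0.116 and 0.0885 for these 3 lists in this order. At 24 and not at 3 months, interferon-stimulated (camera adjusted p = 0.000137), class I antigen presentation (0.00465), acute-phase (0.00562) and urothelial genes (0.00504) passed as shifted higher in luminal cells, with adjusted p = 0.0598, 0.0598, 0.0695 and 0.0598 with an estimated correlation. Androgen receptor targets also passed as shifted higher at 24 and not at 3 months (camera adjusted p = 0.0179; 0.0695 with an estimated correlation). Smooth muscle genes passed as shifted lower in luminal cells at 24 and not at 3 months (camera adjusted p = 0.0181). The camera adjusted p of smooth muscle genes was 0.235 with an estimated correlation and 0.0538 without luminal old replicate 2. A pass at 1 age does not compare the ages, and at 3 months the medians of interferon-stimulated (0.78), class I (0.65) and urothelial genes (2.12) were above 0 too. The interferon gene Irgm1 (log2 2.01) and B2m (3.65) were higher in old luminal than in old basal cells. In all, 15 lists passed at 3 months and 18 at 24 months, 5 of them at each age also with an estimated correlation.

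The comparison of ages asks which genes change in each epithelial layer as mice grow old. In basal cells, genes of the extracellular matrix fell with age. Fibroblast and smooth muscle markers shifted lower in both cell types too, at the preset correlation alone. Whether fewer stromal cells in old samples contributed to the falls of Sparc, Fn1 and other matrix genes that are not collagens was not tested. Sparc, a collagen-binding matricellular protein, fell from 534 ± 21.8 to 168 ± 19.2 CPM (mean ± SD, n = 3; 3.17-fold lower, log2 fold change -1.67 ± 0.14 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.2e-05), and fibronectin, Fn1, fell from 91.6 ± 11.5 to 17.5 ± 3.56 CPM (5.23-fold lower, log2 -2.39 ± 0.28, edgeR adjusted p = 0.00119). Agrin, the proteoglycan Agrn of basement membranes, fell from 961 ± 38.1 to 603 ± 57.2 CPM (log2 -0.67 ± 0.12, edgeR adjusted p = 0.0107). The heme oxygenase gene Hmox1, a target of oxidative stress signaling, rose 3.43-fold from 124 ± 54.7 to 425 ± 20.6 CPM (log2 1.78 ± 0.27, edgeR adjusted p = 0.00472). Vmp1, an autophagy gene, rose 2.98-fold from 52.1 ± 3.46 to 155 ± 30.7 CPM (log2 1.58 ± 0.16, edgeR adjusted p = 0.000354), and Jun rose from 1137 ± 47.5 to 2190 ± 237 CPM (log2 0.95 ± 0.09, edgeR adjusted p = 0.000354). Spermidine synthase, Srm (log2 1.17 ± 0.17, edgeR adjusted p = 0.00405), and the chaperone Hspa8 (0.69 ± 0.10, edgeR adjusted p = 0.00393) also rose. For each of these genes the 3 old libraries lay entirely above or below the 3 young libraries. The rule that named Sparc, Fn1, Hmox1 and Vmp1 required this, so it is no separate evidence for them. In GRCm38, Sparc lies on chromosome 11 (55394159 to 55420080), Fn1 on 1 (71585473 to 71653280), Hmox1 on 8 (75093618 to 75100593), Vmp1 on 11 (86583858 to 86683836) and Jun on 4 (95049036 to 95052222), all protein-coding.

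Of 14201 tested genes, 144 rose and 32 fell in old basal cells, 86 of them at least 2-fold. The count of 176 was 266 without basal young replicate 2, 73 without basal old replicate 1, 92 without basal old replicate 2 and 111 without basal old replicate 3. The share that rose, 81.8%, was 61.6% with DESeq2 size factors (85 rose and 53 fell) and 51% on fragment-equivalent counts (157 rose and 151 fell), so the direction of the basal response as a whole is not settled by these libraries. Of the 144 rises, 39 started from a young group without a distinct fragment, where old libraries held 2.64 times more fragments. Sparc, Fn1, Hmox1, Vmp1 and Jun are the 5 of 39 named basal calls that held without each library in turn and under every other setting, and 17 of 39 held without each library.

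**Figure D2:**
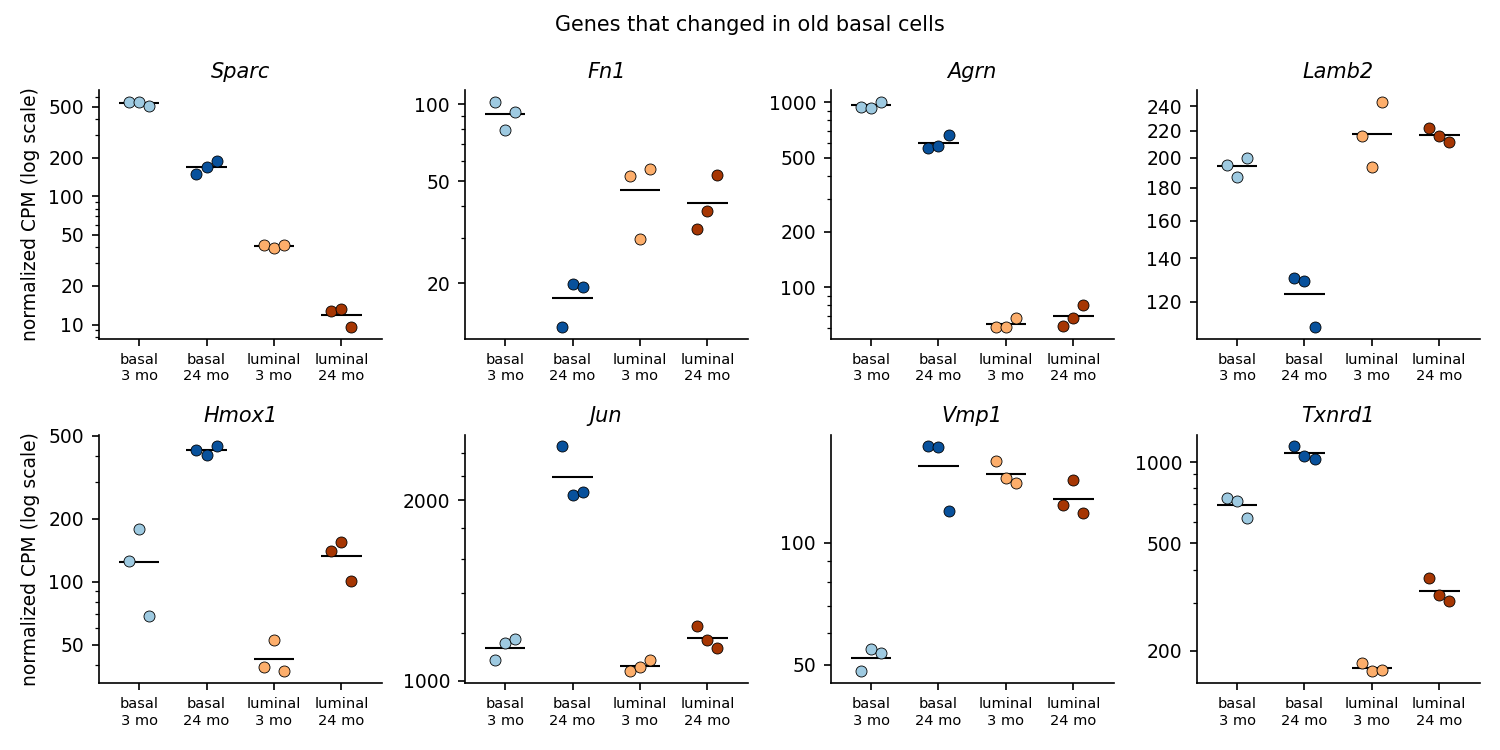
Normalized CPM of 8 genes in basal and luminal cells at both ages, 1 point per library (n = 3 per group) with the group mean as a line, log axis. Sparc, Fn1, Agrn and Lamb2 are lower and Hmox1, Jun, Vmp1 and Txnrd1 higher in old basal cells.

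Among the 10 basal rises that the rule ranks by fitted log2 were Coq7 (at least 3.57-fold, to 8.14 CPM, edgeR adjusted p = 0.00155), Tdrp (at least 3.23-fold, to 7.38 CPM, edgeR adjusted p = 0.00325) and the acute-phase gene Lrg1 (5.19-fold, 3.06 to 16.1 CPM, edgeR adjusted p = 0.00657). Chac1 (0.349 to 9.06 CPM) and Bmpr1b (0.923 to 5.73 CPM) rose from young means under the limit of 2.28 CPM that 3 fragments set, so no fold is given. Exosc2 (log2 2.23) and Rhbdd2 (1.58) were also among these 10. Exosc2 was not called without basal young replicate 2 (0.0565), basal young replicate 3 (0.0643), basal old replicate 1 (0.128) or basal old replicate 2 (0.0954) by edgeR adjusted p. Rhbdd2 was not called without basal young replicate 1 (0.0507), basal old replicate 1 (0.071), basal old replicate 2 (0.0727) or basal old replicate 3 (0.0947) by edgeR adjusted p. Coq7, Tdrp, Lrg1, Chac1 and Bmpr1b held without each library, but Bmpr1b was not called on fragment-equivalent counts (edgeR adjusted p = 0.154). Collagen I, Col1a1, fell 7.73-fold from 46.4 ± 17.8 to 5.99 ± 4.59 CPM (log2 -2.95 ± 0.64, edgeR adjusted p = 0.0372), but not without basal young replicate 3 (0.08) or basal old replicate 2 (0.0982). Serpinb9 fell (log2 -1.52, edgeR adjusted p = 0.00475) without exception among single libraries left out, as did Fn1 and Sparc. On fragment-equivalent counts Fn1 and Sparc were called and Serpinb9 was not (edgeR adjusted p = 0.192). The other large falls, Vmac (-2.26), Col12a1 (-1.77), Kdelr3 (-1.75), Lrrc75b (-1.68) and Mapk14 (-1.40), each lost the call without basal old replicate 1 (edgeR adjusted p = 0.0578 to 0.121). Without basal old replicate 2, edgeR adjusted p was 0.0727 to 0.129 for these except Lrrc75b, and Vmac, Col12a1 and Mapk14 were also lost without basal young replicate 3 (0.0628, 0.0576 and 0.102). By edgeR adjusted p, Vmac was lost without basal young replicate 1 (0.0584) and basal old replicate 3 (0.089), Col12a1 without basal young replicate 1 (0.0734) and basal young replicate 2 (0.0553), and Mapk14 without basal young replicate 2 (0.068) and basal old replicate 3 (0.0904).

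Matrix and basement membrane genes shifted lower as a list in basal cells, with 6 of 21 (Sparc, Fn1, Agrn, Lamb2, Col4a1 and Col18a1) called lower. With p adjusted over the list alone, 10 were lower and 1 higher. The median log2 fold change was -0.73 (camera adjusted p = 2.76e-10), and this was the only basal list that passed with an estimated correlation between genes (camera adjusted p = 0.0202). Lamb2, a laminin chain, fell from 194 to 123 CPM (log2 -0.65 ± 0.12, edgeR adjusted p = 0.0149), but not without basal old replicate 3 (0.0662). Col4a1 fell from 642 to 238 CPM (-1.43 ± 0.32, edgeR adjusted p = 0.0425), and its edgeR adjusted p was 0.064 to 0.144 without any 1 of the 6 basal libraries. Basal markers shifted lower (median -0.29, camera adjusted p = 0.00676), with adjusted p = 0.29 with an estimated correlation. Col17a1 was the single call among them (1091 to 635 CPM, log2 -0.78 ± 0.16, edgeR adjusted p = 0.0304), and its edgeR adjusted p was 0.0713 without basal young replicate 1 and 0.0854 without basal old replicate 3. Fibroblast markers (median -1.39, 1 of 15 called, camera adjusted p = 0.000194), smooth muscle markers (-0.93, 0 of 11 called, 0.0341), complement genes (-0.65, 1 of 14 called, 0.0426) and proliferation genes (-0.48, 0 of 32 called, 0.0364) also shifted lower. Their camera adjusted p was 0.3, 0.336, 0.29 and 0.181 with an estimated correlation. With genes at 0 in 1 group put at the bound of 3 fragments, the medians were -0.54 for fibroblast, -0.32 for complement and -0.25 for proliferation genes.

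Oxidative defense genes shifted higher in basal cells, with 5 of 34 called (Hmox1, Txnrd1, Gclm, Gclc and Srxn1), 8 with p adjusted over the list alone, and a median of 0.24 (camera adjusted p = 0.0411). Their camera adjusted p was 0.29 with an estimated correlation. Txnrd1, thioredoxin reductase, rose from 692 to 1076 CPM (log2 0.64, edgeR adjusted p = 0.00939), but not without basal old replicate 1 (0.0821) or basal old replicate 2 (0.0649). Gclm lost the call without any 1 old basal library (edgeR adjusted p = 0.156, 0.0727 and 0.0711 without basal old replicate 1, 2 and 3). Gclc lost it without basal young replicate 1 (0.0646), basal young replicate 3 (0.0957) or any 1 old basal library (0.0721, 0.102 and 0.131) by edgeR adjusted p. Immediate-early genes had 5 higher calls and 1 lower (Ctgf, log2 -0.94, edgeR adjusted p = 0.0345), with 10 and 1 over the list alone. Their median was 0.26 (camera adjusted p = 0.0426; 0.313 with an estimated correlation). Egr1 rose (0.75, edgeR adjusted p = 0.0149), but not without basal old replicate 1 (0.118). Ribosomal protein genes shifted higher with 0 of 70 called among all genes and 22 over the list alone (median 0.24, camera adjusted p = 5.51e-06). Their camera adjusted p was 0.491 with an estimated correlation. Oxidative phosphorylation genes (median 0.27, 1 of 52 called, camera adjusted p = 0.00676) and unfolded protein response genes (0.23, 2 of 27 called, 0.0458) shifted higher too. With an estimated correlation, camera adjusted p was 0.064 and 0.73. Of the 11 basal lists that passed, 5 moved up and 6 down, and 4 lists passed with DESeq2 size factors and 5 without luminal old replicate 2.

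No other list passed camera in basal cells. Luminal markers had camera adjusted p = 0.0574 with 2 of 20 called higher, and Cldn7 was one of them (log2 0.96, edgeR adjusted p = 0.0125; 0.0889 without basal old replicate 1). With the fry rotation test 7 lists passed in basal cells, 5 of them among the 11 that passed camera. The others were luminal markers (fry adjusted p = 0.00121) and cholesterol genes (0.0328), both shifted higher. Progenitor and proximal luminal markers had camera adjusted p = 0.761, with Cyp2f2 called higher and Prom1 lower. Senescence-associated secretory genes had camera adjusted p = 0.816, although the urokinase gene Plau rose (log2 0.99 ± 0.13, edgeR adjusted p = 0.00263). Camera adjusted p was 0.731 for secretory genes, 0.916 for androgen receptor targets, 0.765 for senescence regulators, 0.0759 for interferon-stimulated genes, 0.761 for class I and 0.62 for class II antigen presentation. It was 0.916 for chemokines, 0.965 for NF-kB targets, 0.933 for acute-phase genes, 0.0625 for heat shock genes, 0.765 for cholesterol genes, 0.731 for polyamine genes, 0.916 for Notch genes and 0.0838 for Wnt genes. Cell markers had camera adjusted p = 0.765 for T and NK cells, 0.933 for B cells and for macrophages, 0.915 for endothelial, 0.127 for erythroid, 0.981 for seminal vesicle, 0.761 for neuroendocrine and 0.981 for urothelial genes. Median and mean differed in sign for androgen receptor targets (-0.08 and 0.09), chemokines (-0.02 and 0.46), Notch genes (-0.03 and 0.38), senescence-associated secretory genes (0.01 and -0.26) and class I genes (0.06 and -0.1). They also differed for macrophage (0.45 and -0.52) and urothelial genes (0.51 and -1.25), and the test pointed down for seminal vesicle genes with a median of 2.05.

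In luminal cells, several progenitor and proximal luminal markers rose with age. Cyp2f2 rose from 91.5 ± 14.5 to 403 ± 126 CPM (mean ± SD, n = 3; log2 fold change 2.14 ± 0.22 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000295), Krt7 from 124 ± 20.8 to 383 ± 91.4 (1.63 ± 0.18, edgeR adjusted p = 0.000406) and Wfdc2 from 25.4 ± 5.83 to 172 ± 70 (2.76 ± 0.35, edgeR adjusted p = 0.00102). Krt15, a keratin of basal cells, rose from 137 ± 13.7 to 433 ± 170 CPM (1.67 ± 0.22, edgeR adjusted p = 0.00128) and Sfn from 214 ± 11.2 to 514 ± 142 CPM (1.26 ± 0.17, edgeR adjusted p = 0.0015). The urokinase receptor Plaur rose from 140 ± 30.7 to 478 ± 144 CPM (1.77 ± 0.23, edgeR adjusted p = 0.00128), and thrombospondin, Thbs1, from 334 ± 38.3 to 868 ± 96.3 CPM (1.38 ± 0.13, edgeR adjusted p = 0.000157). Sparc fell 3.48-fold from 41.2 ± 1.43 to 11.8 ± 2.01 CPM (-1.80 ± 0.14, edgeR adjusted p = 4.98e-05), Igfbp5 fell 3.04-fold from 146 to 47.9 CPM (-1.60 ± 0.21, edgeR adjusted p = 0.00128), and Col6a3 fell 7.91-fold from 345 ± 159 to 43.6 ± 10.8 CPM (-2.98 ± 0.48, edgeR adjusted p = 0.00465). All 3 old libraries lay above, or for the falls below, all 3 young libraries for each of these genes. The rule that named Sparc, Igfbp5 and Col6a3 required this, so it is no separate evidence for them. In GRCm38, Cyp2f2 lies on chromosome 7 (27119955 to 27133660), Krt7 on 15 (101412403 to 101427806), Wfdc2 on 2 (164562715 to 164568510), Krt15 on 11 (100131759 to 100135949), Plaur on 7 (24460937 to 24475970) and Thbs1 on 2 (118111876 to 118127133).

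In old luminal cells 179 genes rose and 56 fell, 129 of them at least 2-fold, and 8 of the rises started from a group without a distinct fragment. The count of 235 was 124 without luminal young replicate 3 and 146 without luminal old replicate 2. On fragment-equivalent counts 381 genes rose and 162 fell. Of 58 named luminal calls, 28 held without each library and 13 also under every other setting: Prss22, Col6a3, Sparc, Igfbp5, Cyp2f2, Krt7, Wfdc2, Krt15, Sfn, Plaur, Lif, Gsto1 and Thbs1. The old luminal libraries differed in seminal vesicle RNA: 6 seminal vesicle genes other than Svs2 took 4.18% of the reads in luminal old replicate 2 against 0.25% and 0.436% in luminal old replicate 1 and 3.

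**Figure D3:**
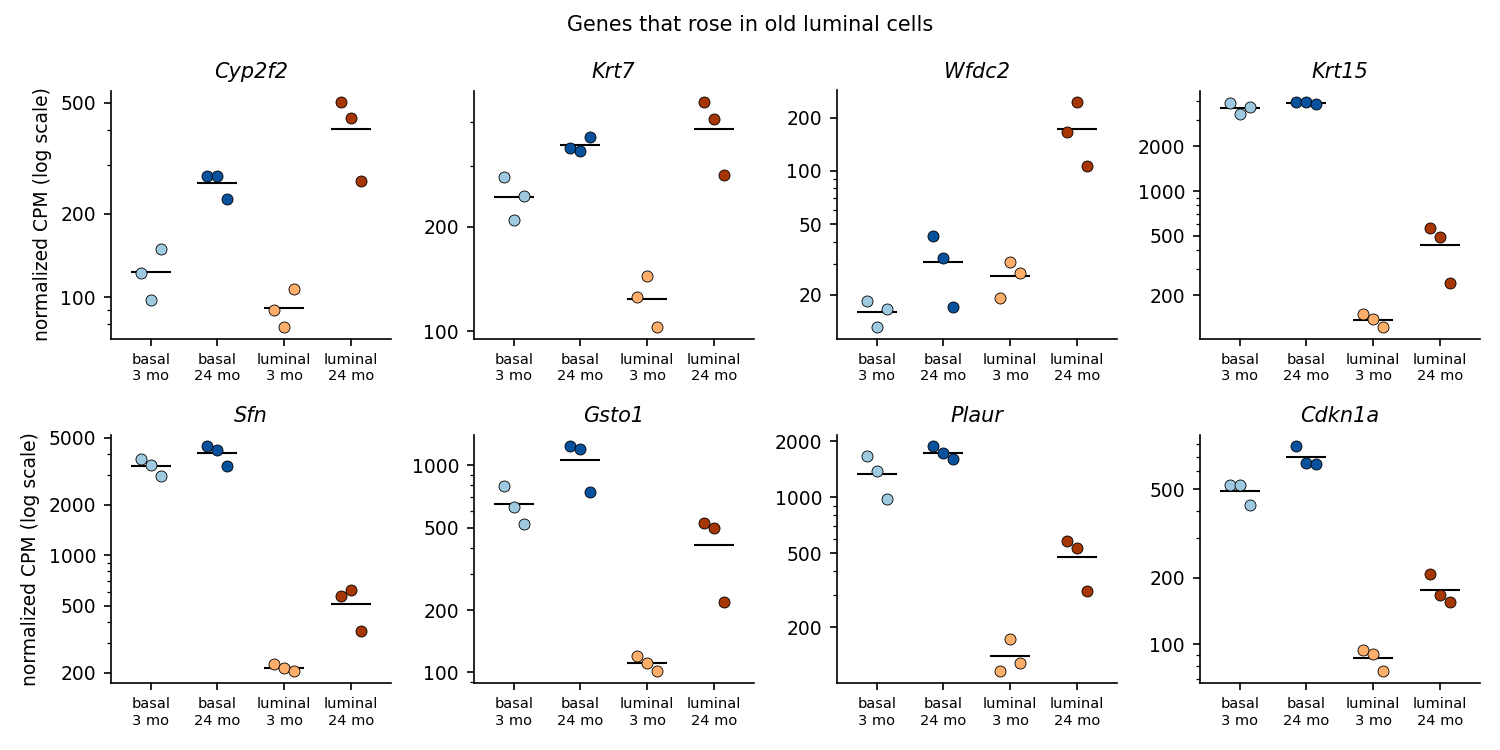
Normalized CPM of 8 genes in basal and luminal cells at 3 and 24 months, 1 point per library (n = 3 per group) with the group mean as a line, log axis. Cyp2f2, Krt7, Wfdc2, Krt15, Sfn, Gsto1, Plaur and Cdkn1a are all higher in old luminal cells.

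Among the 10 luminal rises that the rule ranks by fitted log2, Prss22 rose 7.37-fold from 8.35 to 61.6 CPM (log2 2.88 ± 0.44, edgeR adjusted p = 0.00289), Trpv4 7.3-fold (2.87, edgeR adjusted p = 0.00224) and Selp at least 5.88-fold, to 7.35 CPM (edgeR adjusted p = 0.00128). Ceacam10 rose from 26.2 ± 19.7 to 1340 ± 2010 CPM (log2 5.68, edgeR adjusted p = 0.0202), but without luminal old replicate 2 its log2 was 2.83 with edgeR adjusted p = 0.0839. Ceacam10 was also not called without luminal young replicate 1 (0.086), luminal young replicate 2 (0.0738) or luminal young replicate 3 (0.0519) by edgeR adjusted p. Ly6d, a marker of castration-resistant luminal progenitors, rose from 0.726 CPM, under the limit of 1.25 CPM, to 12.1 CPM (edgeR adjusted p = 0.019; 0.0538 without luminal old replicate 2). Pgm5 (2.96, edgeR adjusted p = 0.0158; 0.0835 without luminal young replicate 3), Mall (2.89), Amy1 (3.64), Adam8 and Nrp2 completed these 10. Without luminal old replicate 2, edgeR adjusted p was 0.0666 for Mall, 0.139 for Amy1 (log2 2.41), 0.0811 for Adam8 and 0.13 for Nrp2, and without luminal young replicate 2 it was 0.0719, 0.0824, 0.0738 and 0.15. Without luminal young replicate 3 edgeR adjusted p was 0.0955 for Mall, 0.0955 for Amy1 and 0.126 for Adam8, without luminal old replicate 1 it was 0.0861 for Mall, 0.0811 for Adam8 and 0.0918 for Nrp2, and without luminal young replicate 1 it was 0.0607 for Amy1 and 0.127 for Adam8. The smooth muscle gene Cnn1 fell at least 3.58-fold from 5.66 CPM (edgeR adjusted p = 0.00499). Col1a1 fell 9.63-fold from 63.7 ± 20.4 to 6.62 ± 2.77 CPM (-3.27 ± 0.64, edgeR adjusted p = 0.0183; 0.0662 without luminal young replicate 3 and 0.0843 without luminal old replicate 1). Tpst1 (log2 -2.16) and Prelp (-1.65, edgeR adjusted p = 0.00877) fell as well, but were not called on fragment-equivalent counts (edgeR adjusted p = 0.056 and 0.096). Itpripl2 (-1.60), Tagln (-1.85) and Col12a1 (-1.69) fell but lost the call without luminal young replicate 2 or luminal young replicate 3 (edgeR adjusted p = 0.0789 to 0.149). By edgeR adjusted p, Tagln was also lost without luminal young replicate 1 (0.137), luminal old replicate 2 (0.147) and luminal old replicate 3 (0.112), Itpripl2 without luminal old replicate 1 (0.107) and luminal old replicate 3 (0.0658), and Col12a1 without luminal old replicate 1 (0.141) and luminal old replicate 2 (0.163). Of these 10 rises 3 held without each library, and 6 of the 10 falls that the rule names.

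Progenitor and proximal luminal markers shifted higher as a list in luminal cells, with 8 of 18 genes called higher and 0 lower, and 13 higher with p adjusted over the list alone. The median log2 fold change was 1.18 (camera adjusted p = 4.36e-13; 0.021 with an estimated correlation), and 1.1 with genes at 0 in 1 group put at the bound of 3 fragments. Beside Cyp2f2, Krt7 and Wfdc2 the calls included Ly6a (Sca-1), which rose 2.27-fold from 77.6 ± 11.7 to 176 ± 51 CPM (edgeR adjusted p = 0.00669). Cd44 (42.4 to 86.8 CPM, edgeR adjusted p = 0.0199), Ly6d and Sox2, which went from no reads to 2.38 CPM (edgeR adjusted p = 0.0104), were also called. Basal markers shifted higher too, with 4 of 24 called and 9 higher and 1 lower over the list alone (median 0.66, camera adjusted p = 1.1e-06; 0.0356 with an estimated correlation). The calls included Krt15, Sfn and Col17a1, which stayed near its limit (0.799 to 2.418 CPM, edgeR adjusted p = 0.00208). The main basal keratins were not called, with edgeR adjusted p = 0.565 for Krt5 (log2 0.30) and 1 for Krt14 (0.03).

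Oxidative defense genes shifted higher in luminal cells, with 5 of 34 called and 8 over the list alone (median 0.23, camera adjusted p = 1.22e-05; 0.0341 with an estimated correlation). Txnrd1 rose from 173 to 333 CPM (log2 0.95 ± 0.11, edgeR adjusted p = 0.000552), Gsto1 from 111 to 413 CPM (1.90 ± 0.28, edgeR adjusted p = 0.00232) and Hmox1 from 43 ± 8.24 to 132 ± 27.8 CPM (1.62 ± 0.27, edgeR adjusted p = 0.0056). Nfe2l2, the transcription factor that drives such genes, rose from 48.5 to 88.6 CPM (edgeR adjusted p = 0.00163), and Srxn1 rose too (0.94 ± 0.11, edgeR adjusted p = 0.000719). Immediate-early genes shifted higher, with 8 of 25 called and 11 higher and 3 lower over the list alone (median 0.2, camera adjusted p = 1.72e-05; 0.0356 with an estimated correlation). Fosl1 (1.10 ± 0.18, edgeR adjusted p = 0.0058), Ctgf (1.10 ± 0.20, edgeR adjusted p = 0.0114) and Egr1 (0.74, edgeR adjusted p = 0.0126) were among them. Ctgf was not called without luminal young replicate 3 (edgeR adjusted p = 0.0531) or luminal old replicate 1 (0.0505), and Egr1 not without luminal young replicate 1 (0.0537). NF-kB targets shifted higher, with 2 of 23 called and 3 over the list alone (median 0.37, camera adjusted p = 1.1e-06; 0.0356 with an estimated correlation). The adhesion molecule Icam1 rose from 41.2 to 72.5 CPM (0.81 ± 0.11, edgeR adjusted p = 0.00148). Acute-phase genes (median 0.87, and 0.63 with genes at 0 at their bound, 1 of 12 called, camera adjusted p = 0.00156) and class I antigen presentation genes (2 of 20 called, median 0.41, mean -0.21, 0.0029) shifted higher. Their camera adjusted p was 0.0417 and 0.0411 with an estimated correlation. B2m rose from 2765 to 4021 CPM (0.54 ± 0.11, edgeR adjusted p = 0.0188), but not without luminal young replicate 2 (0.0677), luminal young replicate 3 (0.0943) or luminal old replicate 2 (0.0832).

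Proliferation genes shifted lower in luminal cells, with 0 of 32 called by either adjustment (median -1.45, camera adjusted p = 5.85e-05; 0.021 with an estimated correlation). Mki67 was at 36.1 and 5.04 CPM in young and old cells (log2 -2.84, edgeR adjusted p = 0.182). Neuroendocrine genes shifted lower, with Ncam1 as the only call of 7 (median -1.19, camera adjusted p = 4.57e-05; 0.0341 with an estimated correlation). Fibroblast markers had 3 of 15 called lower, Col6a3, Col1a1 and Loxl1 (median -1.73, camera adjusted p = 2.48e-06; 0.112 with an estimated correlation). Smooth muscle markers had 3 of 11 called lower, Cnn1, Tagln and Smtn (-1.12, camera adjusted p = 4.55e-05; 0.0652 with an estimated correlation). Secretory genes shifted lower with 0 of 12 called (-0.39, camera adjusted p = 0.0111; 0.323 with an estimated correlation). Senescence-associated secretory genes shifted higher (median 0.38, camera adjusted p = 0.00735; 0.0918 with an estimated correlation), with Plaur, Lif, Igfbp7 and Timp2 called higher and Igfbp5 lower of 25. Of these list members, Loxl1, Smtn, Ncam1 and Igfbp7 lost the call without luminal young replicate 2 or 3 or luminal old replicate 1 or 2 (edgeR adjusted p = 0.0533 to 0.211). Ncam1 and Igfbp7 lost it without luminal young replicate 1 (0.0833 and 0.112), and Smtn without luminal old replicate 3 (0.128), by edgeR adjusted p. Interferon-stimulated genes (median 0.35, 2 of 36 called, camera adjusted p = 0.00777), heat shock genes (0.39, 1 of 16 called, 4.57e-05), endothelial genes (1.42, 2 of 13 called, 0.0205) and seminal vesicle genes (3.86, 2 of 10 called, 0.0029) shifted higher. Their camera adjusted p was 0.121, 0.124, 0.0835 and 0.293 with an estimated correlation. Ribosomal protein genes passed with 0 of 70 called, a median of 0.07 and a mean of -0.17 (camera adjusted p = 0.0413; 0.604 with an estimated correlation). With genes at 0 in 1 group put at their bound, the medians were -1.17 for proliferation, -0.51 for neuroendocrine and 0.35 for endothelial genes. Without luminal old replicate 2, camera adjusted p was 0.0733 for secretory, 0.0515 for interferon-stimulated, 0.0588 for ribosomal protein and 0.0608 for seminal vesicle genes, and 0.0376 for unfolded protein response genes. In all 13 lists moved up and 5 down, and 9 of these 18 passed with an estimated correlation.

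Luminal markers did not pass in luminal cells (camera adjusted p = 0.0533, median 0.14 and mean -0.02), with Cdh1, Krt8, Epcam and Cldn7 called higher. Each of these 4 calls ended without luminal young replicate 1, luminal young replicate 3, luminal old replicate 1 or luminal old replicate 2 (edgeR adjusted p = 0.0588 to 0.161), and all but Cdh1 without luminal young replicate 2 (0.0538 to 0.103). Camera adjusted p was 0.172 for androgen receptor targets, 0.315 for senescence regulators and for macrophages, 0.217 for class II genes, 0.0984 for chemokines and 0.799 for complement (median 0.04, mean -0.39). It was 0.104 for unfolded protein response genes, 0.293 for oxidative phosphorylation, 0.0695 for cholesterol, 0.759 for polyamine and 0.159 for matrix genes. Notch genes had camera adjusted p = 0.653 (median 0.04, mean -0.2), Wnt genes 0.401, T and NK cell genes 0.54, B cell genes 0.535, erythroid genes 0.759 and urothelial genes 0.12.

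**Figure D4:**
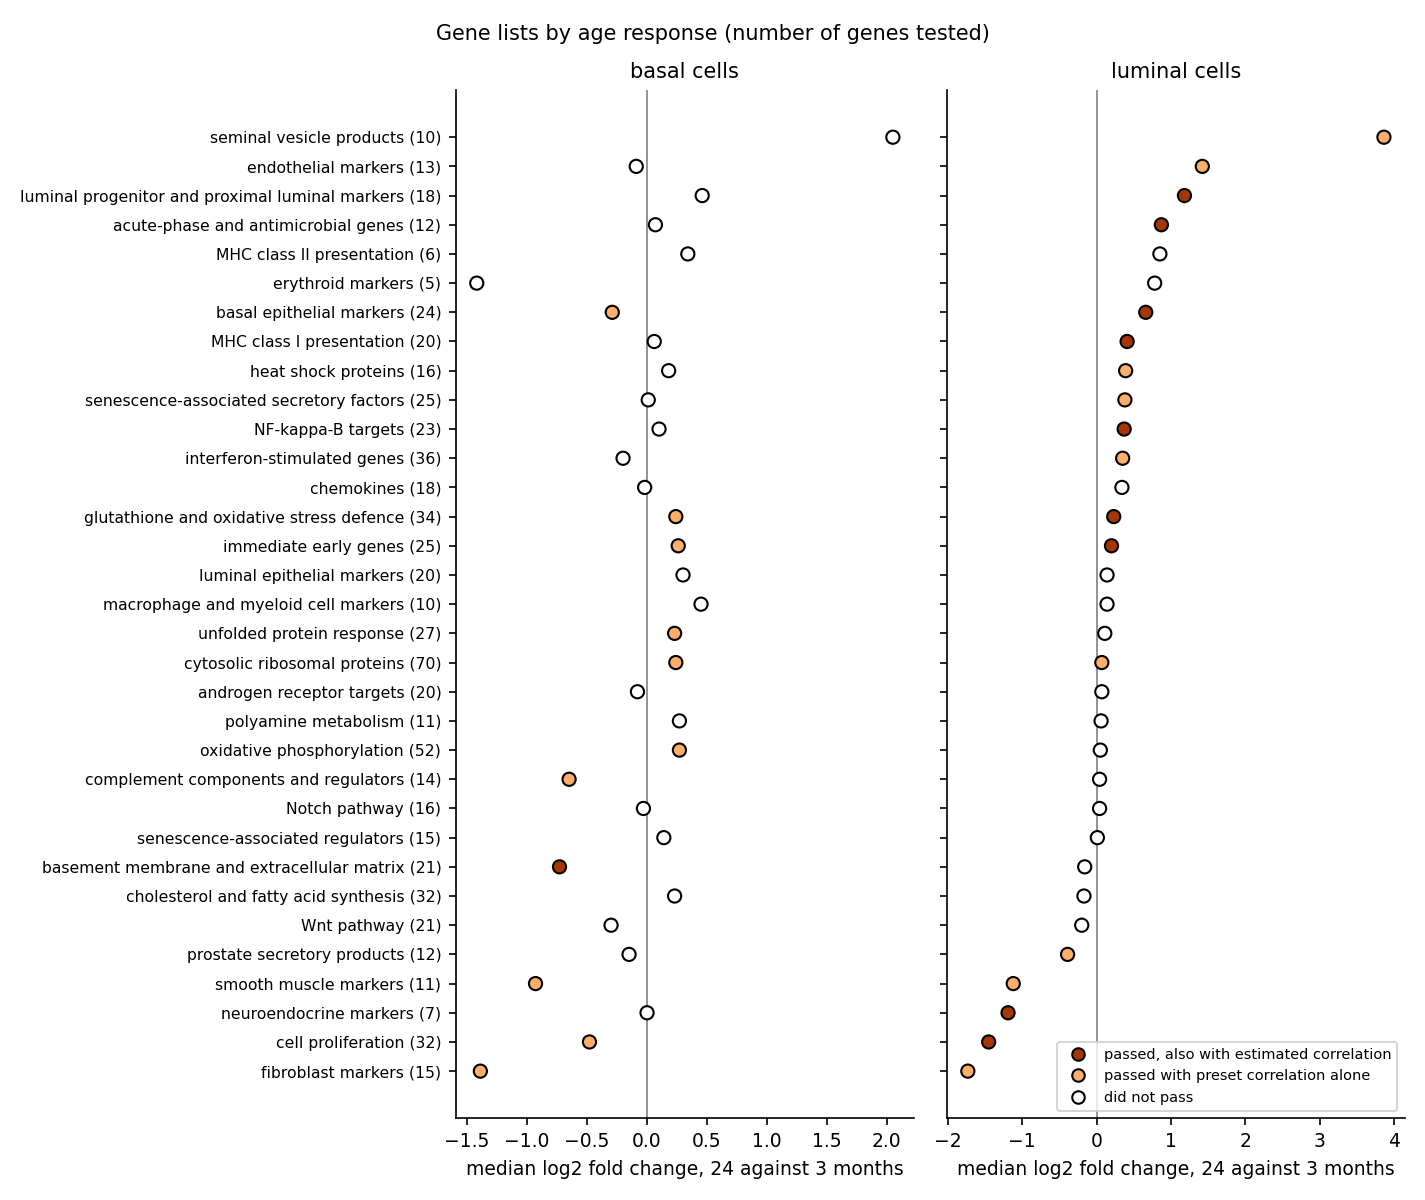
Median log2 fold change with age of each gene list with at least 5 tested genes, in basal and in luminal cells. Dark points passed also with an estimated correlation between genes, light points at the preset correlation only, and white points did not pass.

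The cyclin-dependent kinase inhibitor Cdkn1a rose 2.02-fold in luminal cells, from 87 ± 10.1 to 176 ± 27.5 CPM (mean ± SD, n = 3; log2 1.02 ± 0.14, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00163). In basal cells Cdkn1a was at 489 and 694 CPM (0.51 ± 0.14, edgeR adjusted p = 0.0979), and the difference of the responses was not called (0.51, edgeR adjusted p = 0.306; 0.0245 with the DESeq2 Wald test and up to 1 under other settings). Cdkn2a was not tested, with 48 reads over the 12 libraries. Of the other genes fixed before the data were examined, Prom1 fell in basal cells (10.9 to 4.34 CPM, -1.33 ± 0.20, edgeR adjusted p = 0.00481), but was not called there on fragment-equivalent counts (0.138). In luminal cells Prom1 was not called (0.20, edgeR adjusted p = 0.897), and the interaction had edgeR adjusted p = 0.0225 (0.0596 without luminal young replicate 3). Krt8 rose in luminal cells (0.41 ± 0.09, edgeR adjusted p = 0.0304), but not without luminal young replicate 1 (0.0839), luminal young replicate 2 (0.0538), luminal young replicate 3 (0.137), luminal old replicate 1 (0.0872) or luminal old replicate 2 (0.146). Psca (122 to 437 CPM, edgeR adjusted p = 0.376) and Krt4 (44.7 to 150 CPM, edgeR adjusted p = 0.341) were not called in luminal cells. On fragment-equivalent counts edgeR adjusted p was 1.04e-05 for Psca and 0.000815 for Krt4, and each was called under 5 of 15 settings (adjusted p 1.98e-09 to 0.969 for Psca and 0.000433 to 0.951 for Krt4). In basal cells, edgeR adjusted p was 0.69 for Krt4, 0.135 for Psca, 0.338 for Ly6a, 0.176 for Krt8, 0.113 for Krt18, 0.812 for Krt5, 0.305 for Krt14 and 0.507 for Trp63. On fragment-equivalent counts edgeR adjusted p in basal cells was 0.00446 for Krt14 (log2 -0.55) and 0.0207 for Psca (2.76), called under 5 and 4 of 15 settings (adjusted p 0.00134 to 1 and 0.00945 to 0.45). Pbsn, an androgen-regulated secretory gene, was not called in basal or luminal cells (edgeR adjusted p = 0.957 and 1), and Krt18 had edgeR adjusted p = 0.125 in luminal cells (0.0326 on fragment-equivalent counts, called under 3 of 15 settings, adjusted p 0.0163 to 1).

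The age response differed between cell types for 116 genes, 60 with a higher and 56 with a lower luminal response. Ctgf, a target of the Hippo pathway, fell from 144 to 74.8 CPM in basal cells and rose from 19.4 to 41.5 CPM in luminal cells (mean, n = 3; difference of log2 fold changes 2.04 ± 0.28 SE, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00632). Fn1 fell in basal cells only (difference 2.23 ± 0.38, edgeR adjusted p = 0.017), and Thbs1 rose in luminal cells only (1.05 ± 0.19, edgeR adjusted p = 0.0212). Col17a1 fell in basal cells and rose in luminal cells (2.38 ± 0.28, edgeR adjusted p = 0.00368), where it was near the counting limit. Jun (-0.79 ± 0.13, edgeR adjusted p = 0.0166) and Srm (-1.39 ± 0.24, edgeR adjusted p = 0.0186) rose in basal cells, against luminal log2 fold changes of 0.16 and -0.21. Krt15 (1.55 ± 0.30, edgeR adjusted p = 0.0312) rose more in luminal cells. Ctgf was the only one of 30 named calls that held without each library and under every setting. Fn1, Thbs1, Selp, Vwa7, Trim29, Ccdc92, Cenpv, Col17a1 and Bmpr1b held without each library. Jun was lost without basal old replicate 1 (edgeR adjusted p = 0.0633), basal old replicate 2 (0.0509) or luminal young replicate 2 (0.052), and Srm without basal old replicate 1 (0.0693), luminal young replicate 2 (0.0509) or luminal old replicate 2 (0.0517). Krt15 was lost without basal old replicate 1 (edgeR adjusted p = 0.0526), basal old replicate 3 (0.0706), luminal young replicate 1 (0.0537), luminal young replicate 3 (0.0862), luminal old replicate 1 (0.064) or luminal old replicate 2 (0.0563). The count of 116 was 76 without basal old replicate 1, 76 without basal old replicate 2, 59 without basal old replicate 3, 67 without luminal young replicate 1, 54 without luminal young replicate 3, 74 without luminal old replicate 1 and 77 without luminal old replicate 2. The share higher in luminal cells was 78.3% on fragment-equivalent counts (123 higher and 34 lower), 77.8% at 20 CPM and 31.4% without basal young replicate 2 (54 higher and 118 lower), so its balance is not settled by these libraries. It was 51.7% with all 12 libraries and 61.9% with DESeq2 size factors, which moved the all-gene median of this comparison by 0.111 and that of the cell types at 24 months by 0.132.

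Basal markers (median difference 0.93, 3 of 24 called, 10 over the list alone, camera adjusted p = 4.72e-09) and progenitor markers (0.95, 5.06e-08) shifted toward a higher response in luminal cells, with camera adjusted p = 0.0734 and 0.0959 with an estimated correlation. Matrix genes (Fn1, Thbs1 and Agrn called, median 0.49, camera adjusted p = 0.000403), interferon-stimulated genes (0.59, 0.00125), NF-kB targets (0.25, 0.00125), acute-phase genes (0.95, 0.0109), class I genes (0.45, mean -0.11, 0.0244), senescence-associated secretory genes (0.45, 0.0261) and seminal vesicle genes (0.52, 0.0282) shifted in the same way. Agrn lost the call without basal young replicate 1 (edgeR adjusted p = 0.0566), basal young replicate 3 (0.0616), luminal young replicate 1 (0.0884), luminal young replicate 3 (0.0596) or luminal old replicate 3 (0.0503). Neuroendocrine genes shifted toward a lower luminal response (-1.18, camera adjusted p = 0.00402). None of these 10 lists passed with an estimated correlation, where camera adjusted p was 0.103 for matrix, interferon, acute-phase, class I and neuroendocrine genes, 0.135 for NF-kB targets, 0.158 for senescence-associated secretory genes and 0.46 for seminal vesicle genes. Without luminal old replicate 2, the library with 4.18% seminal vesicle reads, senescence-associated secretory (camera adjusted p = 0.136) and seminal vesicle genes (0.333) did not pass.

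Hmox1, Txnrd1, Srxn1, Egr1, Fos, Ier3, Hspa8, Cyp2f2 and Cldn7 were among 21 genes that rose with age in both cell types, against 1.82 expected for independent lists (odds ratio 15, Fisher exact p = 9.25e-17). Sparc, Col1a1, Col12a1, Scd2, Rmnd5a and Sirpa fell in both, 6 against 0.126 expected (odds ratio 65, Fisher exact p = 2.39e-09). Ctgf, Col17a1, Smoc2 and Pgap2 changed in opposite directions. Scd2, a fatty acid desaturase, fell by the same size in basal (log2 -0.66 ± 0.12, edgeR adjusted p = 0.0113) and luminal cells (-0.66, edgeR adjusted p = 0.00836). Over all 14201 genes the fold changes of the cell types were hardly correlated (Pearson r = 0.0176, Spearman 0.0846), and over the 6270 genes with at least 20 CPM r was 0.219 (Spearman 0.146). The Fisher exact test treats genes as independent, and mice of the same pools may have given both cell types. Both age responses also share 1 estimate of the spread per gene, so a gene with little spread is more easily called in both. The numbers expected for independent lists may therefore be too low. The 27 shared genes were 14 without basal young replicate 2, 17 without basal young replicate 3, 8 without basal old replicate 1, 9 without basal old replicate 2, 17 without basal old replicate 3, 13 without luminal young replicate 1, 14 without luminal young replicate 2, 11 without luminal young replicate 3, 17 without luminal old replicate 1 and 10 without luminal old replicate 2.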

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

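The tests on fragment-equivalent counts, of unequal fragments, of carried-over basal cells, and of fewer stromal cells or fibroblast RNA were chosen after the result was seen. The genes listed here had an age response that differed between cell types by the interaction test of the edgeR model (luminal minus basal log2 fold change, Benjamini-Hochberg adjusted p, n = 3 per group).

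Ctgf (2.04, edgeR adjusted p = 0.00632), Fn1 (2.23, 0.017), Thbs1 (1.05, 0.0212), Krt15 (1.55, 0.0312), Nfe2l2 (0.88, 0.0312), Agrn (0.82, 0.0353), Pmepa1 (1.94, 0.0374), Icam1 (0.72, 0.0491), B2m (0.69, 0.0492) and Selp (5.1, 0.017) had the higher response in luminal cells and were called also on fragment-equivalent counts, with adjusted p from 0.000155 for Ctgf to 0.0294 for Icam1. Jun (-0.79, edgeR adjusted p = 0.0166), Srm (-1.39, 0.0186), Btg2 (-0.84, 0.0419) and Atf3 (-0.76, 0.0428) had the lower response in luminal cells and were called also on fragment-equivalent counts, with adjusted p from 0.00732 for Jun to 0.0357 for Btg2. Col17a1 (2.38, edgeR adjusted p = 0.00368; 0.437 on fragment-equivalent counts), Trim29 (3.88, 0.00632; 0.11), Prom1 (1.53, 0.0225; 0.126), Lamb3 (1.52, 0.0468; 0.118), Vwa7 (9.87, 0.0212; 0.12), Sox2 (8.97, 0.0376; 0.228) and Pecam1 (8.9, 0.0376; 0.448) were higher and not called on fragment-equivalent counts. Bmpr1b (-3.05, edgeR adjusted p = 0.00804; 0.11), Plau (-0.98, 0.0232; 0.144), Chac1 (-4.49, 0.0318; 0.123), Cxcl17 (-5.72, 0.0312; 0.817), Ccdc92 (-9.67, 0.00741; 0.198), Cenpv (-8.84, 0.0207; 0.368), Unc5a (-9.55, 0.0412; 0.376), Gm20752 (-9.04, 0.0491; 0.369) and Cnn1 (-8.86, 0.0376; 0.386) were lower and not called on fragment-equivalent counts. Over all settings tried, which include DESeq2 and limma, adjusted p ranged from 9.99e-11 to 0.0225 for Ctgf, and the highest value was 0.0568 for Fn1 and 0.111 or more for the others. Col17a1 and every gene with a difference of 3 or more had a group mean under the limit of 3 fragments, so these values give no size. Of these genes Selp alone was called on fragment-equivalent counts, and the direction of Cxcl17 reversed with limma-trend on TPM and on thinned fragment-equivalent counts.

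With 3 libraries against 3 there are 10 splits of each comparison, too few for a share under 0.05. The true split gave the most calls in each: 176 against at most 17 for age in basal cells, 235 against 3 for age in luminal cells, and 5341 and 5028 against 0 between cell types. For the difference of the age responses, 2 of 100 assignments of age within cell types, drawn from 200 possible, gave at least 116 calls. The other was the exchange of luminal ages with true basal ages, which adds the responses and gave 391, and the highest of the rest was 44. For genes changed alike in both cell types 1 of 100 gave at least 27, and the highest of the others was 4. Since other splits called at most 17 genes in basal or 3 in luminal cells, they could hardly share 27. This comparison therefore does not test whether the cell types agree more than by chance.

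Most basal calls were rises with age (81.8% of 176). Old basal libraries held 2.64 times more distinct fragments, and 39 rises started from young groups without a distinct fragment. On fragment-equivalent counts thinned to equal numbers of fragments, 46.2% of calls were rises (79 higher and 92 lower, 95% interval 38.6 to 54), but the same counts without thinning already gave 51% (157 higher and 151 lower). With the peak estimator the share was 71.6% before thinning (303 higher and 120 lower) and 44.3% after (74 higher and 93 lower). The share before thinning thus depended on the estimator, and unequal fragments cannot be told apart from the change of counting unit. Scaling alone cannot be told apart from a real shift, since DESeq2 size factors gave 61.6% and the fits hold no outside standard. Single genes such as Hmox1, Vmp1 and Jun remained called on fragment-equivalent counts, and an age effect on them stays open.

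Progenitor markers rose in old luminal cells (8 of 18 called). Carried-over basal cells were excluded as the source: they would have to make up a median of 97.4% of the sample to explain the called rises, which needs 2800 CPM of Krt14. Its level in old luminal cells was 0.762% of that (0.449% for Krt5 and 0.0837% for Trp63). Seminal vesicle material in luminal old replicate 2 was excluded too, since the median of the called members kept 97.4% of its size without that library (1.88 and 1.83) and 6 of 8 stayed called. A change within luminal cells, or in which luminal cells the sort collected, stays open and was not tested.

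Of the collagen genes, Col1a1 and Col12a1 fell with age in both cell types, Col4a1 and Col18a1 were called lower in basal cells, and Col6a3 was called in luminal cells (basal log2 -2.02, edgeR adjusted p = 0.0649). Col17a1 was called lower in basal (log2 -0.78) and higher in luminal cells (1.6), where it was near the counting limit. Fewer fibroblasts in old samples cannot be told apart from lower expression: fibroblast markers other than collagens had a median log2 change of -0.29 in basal cells (4 markers, median SE of 1 marker 1.15) and -1.41 in luminal cells (3 markers, 1.2), and these are too few. Fibroblasts of 1 profile were excluded as the only source of both Col1a1 and Col6a3, since Col6a3 to Col1a1 was 5.41 in young luminal and 0.306 in young basal cells, a ratio of 17.7, but which of these has another source, or whether the fibroblasts differed, stays open. For Col1a1 and Col3a1 fibroblast RNA cannot be told apart from other sources, since the same comparison of Col3a1 to Col1a1 gave 0.872. Dcn, 1 of these markers, stayed at 1368 and 1248 CPM in basal cells (log2 -0.13 ± 0.24 SE). In young luminal cells Dcn was at 82.05 CPM, while Col1a1 was at 63.74 CPM there and at 46.38 CPM in young basal cells. Dcn thus did not follow Col1a1 between cell types, and its level is no gauge of fibroblast number here. An age effect on collagen expression stays open.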

How the results depend on the processing

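Fragment-equivalent counts from both estimators, their thinned forms and the filter at 20 CPM were chosen after the data were examined. Of 224 gene results (190 called), settings fixed beforehand left 2022 values with the same direction and call, ended 239 calls, added 38 and reversed 1. Leaving out single libraries kept 1190, ended 338 calls, added 4 and reversed 4, and settings added later kept 853, ended 165 calls, added 53 and reversed 3. Genes called with age in basal cells (176) numbered 774 with the DESeq2 Wald test, 104 with limma-trend on log2 TPM, 45 in a test against a 1.5-fold change, 52 at an adjusted p under 0.01, 308 on fragment-equivalent counts and 423 with the peak estimator. Those in luminal cells (235) numbered 731 with the Wald test, 52 against 1.5-fold, 96 at 0.01, 543 on fragment-equivalent counts and 501 with the peak. The difference of the responses (116) had 640 genes with the Wald test, 30 against 1.5-fold and 20 at 0.01. Genes changed alike (27) numbered 17 with DESeq2 size factors, 57 on fragment-equivalent counts, 67 with the peak and 5 at 0.01, and the 72 list calls fell to 20 with an estimated correlation. The fry rotation test gave 91 list calls, with 58 of the 72 kept. Calls without each library ranged from 73 to 266 for age in basal cells, 124 to 331 in luminal cells, 54 to 172 for their difference, 4588 to 5156 and 4248 to 4527 between cell types, and 8 to 33 for genes changed alike.

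The share of rises among basal calls (81.8%) was 61.9% with upper-quartile factors, 48.4% in a model of the basal libraries alone (61 of 126), 67.9% without a filter, 67.7% at 1 CPM and 54.8% with limma-trend. It was 46.1% at 20 CPM, 51% on fragment-equivalent counts, 71.6% with the peak estimator and 44.3% with the peak and thinning. Over all pairs from different groups, young with old included, residual r was -0.03 to 0.03 for the same replicate number and -0.032 to 0.046 for others. Between young basal and young luminal libraries it was 0.03, 0.028 and 0.016 for the same number and -0.022 to -0.003 for others. Between old basal and old luminal libraries it was -0.011, 0.013 and 0.023 for the same number and -0.023 to 0.008 for others. The ranges overlap in old but not in young libraries, so whether replicate numbers pair libraries cannot be told. A replicate block gave 194, 273, 127, 5131 and 4900 calls. Values that reversed belong to genes that were not called, with 1 exception. Pbsn in basal cells (-0.24) ranged from -0.75 to 0.99 without single libraries, and Krt14 in luminal cells from -0.24 to 0.37. On thinned fragment-equivalent counts Krt14 in luminal cells was -0.26, and with the peak and thinning Krt5 was -0.41. The exception, the difference for Cxcl17 (-5.72), was 0.1 with limma-trend on TPM and 2.54 on thinned fragment-equivalent counts. The cause of these changes was not tested, except that fewer libraries and a stricter threshold leave fewer calls by construction. Depth limits genes under 0.864 to 2.28 CPM, the level of 3 fragments over a group.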

Other observations

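The tests of the luminal shift and of rises against falls, and the fragment-equivalent counts on which the tests of converging cell types ran, were chosen after the result was seen.

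Sbp, a secreted spermine-binding protein, took 5.94 to 6.77% of reads in young luminal libraries and 0.613 to 0.961% in old ones, all 3 old below all 3 young, and was not called (log2 -2.94 ± 0.71, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0542). Sbp was called under 9 of 14 settings (adjusted p 2.19e-10 to 0.245). Spink3 was not called either (-1.71, edgeR adjusted p = 0.291). Svs2 took 9.87 to 12.1% of luminal reads. The ribosomal RNA gene Rn45s took 0.546 to 2.02% of reads across libraries.

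Old cells of the 2 types were proposed to become more alike, with each type moving toward the other. On fragment-equivalent counts thinned to equal totals, luminal rises were enriched for genes higher in basal cells averaged over both ages, with 140 of 222 (63.1% against 46.4% of all 10003 genes, odds ratio 2, Fisher exact p = 5.46e-07), while 15 of 102 luminal falls were (14.7%). Of basal rises, 26 of 79 were higher in luminal cells by the same average (32.9% against 53.6% of all genes, odds ratio 0.422, Fisher exact p = 0.000247), but so were only 16 of 92 falls (17.4%), so basal calls of either direction lie mostly among genes higher in basal cells and the bound set against all genes was wrong. Against falls the odds ratio of basal rises was 2.32 (Fisher exact p = 0.0213; 1.76 and 0.145 with the peak estimator), so a shift of both types cannot be told apart from 1 of luminal cells. The Fisher exact test treats genes as independent, and the shift toward the basal profile in luminal cells (odds ratio 1.77 with the peak estimator), found and tested on the same libraries, is a hypothesis.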
